A study of Mus musculus with 2 samples.

How the data were processed

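DNase-seq was measured in 2 libraries of lung tissue from 10-day-old male B6CASTF1/J mice, biological replicates 1 and 2 of 1 group. Per the labels, the nuclei were isolated from tissue and the animals are numbered 5 and 6, although both samples carry the same donor identifier, so they were taken as separate animals. For each library the authors supplied 2 peak lists, 1 footprint list and 1 list of FDR values along the genome. Per the deposited listing, each was derived from that library's own filtered alignments to mm10, and no list pooled the libraries. The aligner, the peak caller, the footprint caller and their settings are not given in the sources used here.

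The deposited peak lists give the height of each peak as a read-depth normalized signal made by the authors. All heights (100%) were whole multiples of 1 step per library, within 0.05 of a step, and the step was 0.00456 in replicate 1 and 0.00400 in replicate 2. The step was read as the height of 1 cleavage, which gives the number of cleavages at each peak. If heights are scaled to CPM, which the files do not state, the depths are 219 M and 250.0 M cleavages, a ratio of 0.877. The depth before filtering is unknown. The deposited FDR lists give the false discovery rate, a p-value-like unit made by the authors, of the local cleavage density, and were listed up to 0.05. Peaks of the longer list lay in sequence listed at an FDR up to 0.05, and peaks of the shorter list had a lowest FDR up to 0.000992. The deposited footprint lists carry the constant 0.01 in the same unit, taken here as the FDR threshold of the authors' footprint call. Heights were used as deposited, without further normalization, pseudocount or filter.

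The longer list was the main one, with a median width of 180 bp, and the shorter list of 194415 and 138471 peaks was an alternative. Sequence came from GRCm38.p6 and genes from GENCODE vM21. Tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0, Matplotlib 3.10.9 and bedtools 2.31.1. Peaks were shared when they overlapped by at least 1 bp. The overlap to set beside it was the mean over 5 shifts of 1 list by 1 Mb to 5 Mb. Shared peaks were paired one to one for the comparison of heights. The midpoint of each peak was placed at a promoter (within 1 kb of a protein-coding TSS), in an exon, in an intron or between genes, in that order, with protein-coding genes alone counted.

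In all, 35 gene lists of 348 genes were compared with 10000 random lists of the 21938 protein-coding genes. By promoter peaks, random lists were matched on 10 classes of promoter GC content. By shared peaks from 10 kb before to 10 kb after the gene, on the square-root scale, they were matched on 10 classes of gene length. By the median log2 ratio of height between the libraries, centred on all shared peaks, they were matched on 10 classes of mean height among 18529 genes with a ratio. The p is the two-sided percentile of a list among its random lists, which permutes list membership among the genes of a class, and describes these 2 libraries. Benjamini-Hochberg adjustment ran over the 35 lists within each comparison, with a threshold of 0.05. With 10000 random lists the smallest p is 0.0002.

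For 33 consensus sequences of transcription factors, matches on both strands of shared peaks were found, and the share whose centre lay in a footprint of both libraries was set against 100 versions with permuted positions. The p is a one-sided rank among these, so the smallest is 0.0099. A shuffled version needed at least 10 matches to count, further versions were drawn to reach 100, and a motif with too few such versions was not tested, a rule set after the data were seen. The GC box of SP and KLF factors allowed 44 distinct versions and was tested with those. Intervals are 95% Wilson intervals.

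The lists, the consensus sequences, the tests, the main settings and 41 of the 55 alternative values were chosen before the data were examined, and 14 were added afterwards. The alternatives were a reciprocal overlap of 50%, the stronger 50% of peaks, equal numbers of peaks, the shorter list, windows of 500 bp and 2.5 kb, all annotated genes, random lists without matching, the gene body alone, flanks of 50 kb, promoter peaks alone, rank differences, and each replicate left out. Those added were the stronger 50% of 1 library against all peaks of the other, ratios adjusted for GC content in 20 classes and for height, peaks outside promoters, the excess over the footprinted share of the same peaks, 1000 shuffled versions, shuffles with equal CpG number, runs of neighbouring genes for the Hox lists, and the signalling list without Fgfr2.

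Genes were named by a fixed rule. From each list these were the 2 genes with the most shared peaks and the gene with the fewest (not all are printed), and between libraries the 3 lists farthest from 0 on each side with their 2 most extreme genes. Outside the lists they were the 10 genes with the most shared peaks, the 5 shared peaks with the highest mean rank of height in the libraries and the 3 strongest peaks of each library alone. For motifs they were the 10 largest and the 3 smallest differences. Other genes and motifs named, such as Sftpc, Scgb1a1, Shh, Tcf21, Fgf10, the collagen genes, the neuron list between the libraries and interferon regulatory factors, were chosen after their values were seen.

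The tests were run on simulated data. For promoter tests, a share of 0.5 or all of a list's members was set to no promoter peak, and 16 and 30 of 30 such lists were called. Lists with more promoter peaks than random lists were not simulated. With lists shifted up by 0.5 SD and by 1 SD, tests around the gene called 8 and 19 of 30, and tests between libraries called 0 and 11 of 30. Of 290 unchanged lists, promoter tests called 1, tests around the gene 2 and tests between libraries 1. Values were permuted between single genes of a class, so these counts do not cover lists of neighbouring genes that share peaks, such as the Hox lists. The overlap code found 11866 of 11866 planted partners, and the motif test called 7 of 8 planted sequences and 0 of 16 unchanged ones. The motif simulation used random sequence with equal base frequencies and otherwise random footprints. It held only short consensus sequences, without those of CTCF, YY1 and HNF1. It therefore does not give the rate of false calls in genomic sequence. Reads and alignments were not used here, and allele-specific accessibility of the 2 parental genomes was not analysed here, since the lists do not separate alleles.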

Results

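DNase-seq, which cuts nuclear DNA with DNase I wherever chromatin is open and sequences the cut ends, was carried out on lung tissue of 10-day-old male B6CASTF1/J mice, the F1 offspring of the C57BL/6J and CAST/EiJ strains. The series held 1 group of 2 libraries, replicate 1 and replicate 2, which the labels number as animals 5 and 6. Values below are given for replicate 1 and then replicate 2, or as mean ± SD of the 2 libraries. The deposited peak lists at a false discovery rate (FDR) up to 0.05 held 284760 and 215093 peaks, and the deposited footprint lists held 665131 and 617997 footprints. Peak height was the authors' own value for each peak, the read-depth normalized number of DNase I cleavages, and its median was 0.525 and 0.532. The median peak corresponded to 115 and 133 cleavages. Total depth was read from the smallest step in height and was 219 M and 250.0 M cleavages if heights are CPM-scaled, an assumption that the values cannot settle. Coordinates are 1-based on mm10 (GRCm38). With 1 group there was no contrast between conditions, so the comparisons were between the replicate libraries, between classes of genomic sequence, and between fixed gene lists and random lists of genes.

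The first comparison asked where open chromatin lay in the genome of the postnatal lung. The 5 strongest shared peaks, by the mean rank of height in the 2 libraries, included 3 within 100 bp of the transcription start site (TSS) of a protein-coding gene. One lay 8 bp from the TSS of Hjurp, the chaperone of the centromeric histone CENP-A, at chromosome 1, 88277521 to 88277760, with heights of 56.8 and 57.0. A peak 11 bp from the TSS of Dynlt1b, a dynein light chain gene, at chromosome 17, 6430021 to 6430180, had heights of 48.3 and 70.9. An intronic peak 72 bp from a TSS of Dnpep, an aspartyl aminopeptidase gene, at chromosome 1, 75317521 to 75317940, had heights of 43.8 and 47.0. The other two lay in an intron of Sugct, 191 bp from the TSS of Mplkip (chromosome 13, 17694881 to 17695120, heights 47.5 and 49.9), and outside protein-coding genes, 35530 bp from Pak3 (chromosome X, 143482981 to 143483140, heights 37.7 and 37.5).

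Promoters, taken as 1 kb on both sides of a protein-coding TSS, held 15% ± 2.33 (SD, 2 libraries) of the peak midpoints and 2.44% of the genome, a ratio of 6.15 ± 0.956. Introns held 39.0% ± 1.82 of the peaks against 34.4% of the genome, and exons held 4.71% ± 0.366 against 3.02%. Sequence between protein-coding genes held 41.3% ± 0.877 of the peaks against 60.1% of the genome. In the highest of 10 height classes, promoters held 51.1% ± 5.71 of the peaks. In all 4 classes the difference from the genome was larger than the SD of the 2 libraries. A promoter peak was found at 72.9% ± 1.19 of the 21938 protein-coding genes, and 15482 genes (70.6%) had a promoter peak shared by both libraries. The promoter share rose with the window, from 10.7% at 500 bp to 20.8% at 2.5 kb, while its ratio to the genome fell from 8.23 to 3.75, and with all annotated genes the ratio was 3.46.

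Outside the fixed lists, the protein-coding genes with the most shared peaks from 10 kb before to 10 kb after the gene were long genes. Gm20388, annotated as a gene of 4435 kb on chromosome 8 that takes in neighbouring genes, held 886. Among these neighbours was Gse1, which came next with 122, followed by Nav2 with 120, and Foxp1, which encodes a forkhead factor of lung epithelium, with 117. Pde4d, a cAMP phosphodiesterase gene, also held 117, Lrmda held 116, Gm37240 held 113, Rbms3 held 109, Prkce, which encodes protein kinase C epsilon, held 108, and Zfhx3 held 106. The median protein-coding gene held 5 shared peaks, 15.5% of genes held none, and the 90th percentile was 16.

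The next comparison asked how far the replicate libraries found the same sites. Of the peaks of replicate 1, 63% (179394) overlapped a peak of replicate 2, and of the peaks of replicate 2, 83.6% (179734) overlapped a peak of replicate 1, a mean of 73.3% ± 14.5. Both shares count the same overlaps over lists of unequal length, so this SD is not a spread of independent values. After shifting 1 list along its chromosomes, 3.43% and 4.55% overlapped. The strongest peaks without an overlap still lay next to genes. In replicate 1 they lay 609 bp from Khsrp, which encodes a splicing regulator (chromosome 17, 57032001 to 57032260, height 24.8), 192 bp from Ubtd1 (chromosome 19, 41981421 to 41981720, height 14.97), and 514 bp from Prrc2a (chromosome 17, 35165301 to 35165520, height 11.7). In replicate 2 they lay 86 bp from Evi5l (chromosome 8, 4166401 to 4166560, height 20.6), 65 bp from Iqcd (chromosome 5, 120588861 to 120589040, height 18.8), and 737 bp from Csnk1g2, a casein kinase gene (chromosome 10, 80621981 to 80622220, height 14.6). All 6 lay within 1 kb of a TSS, and each had a peak of the other library within 160 bp.

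Overlap followed height. In the lowest of 10 height classes 15.5% of the peaks of replicate 1 and 40.0% of the peaks of replicate 2 were shared, and in the highest 99.1% and 99.6% were. Peaks found in 1 library alone numbered 105366 in replicate 1 and 35359 in replicate 2. Their median was 62 cleavages in both libraries, against 191 and 161 at shared peaks, and promoters held 6.18% and 12.4% of them, against 17.5% of shared peaks. With the stronger 50% of the peaks of 1 library set against all peaks of the other, an alternative added after the data were seen, 93.5% overlapped.

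**Figure D1:**
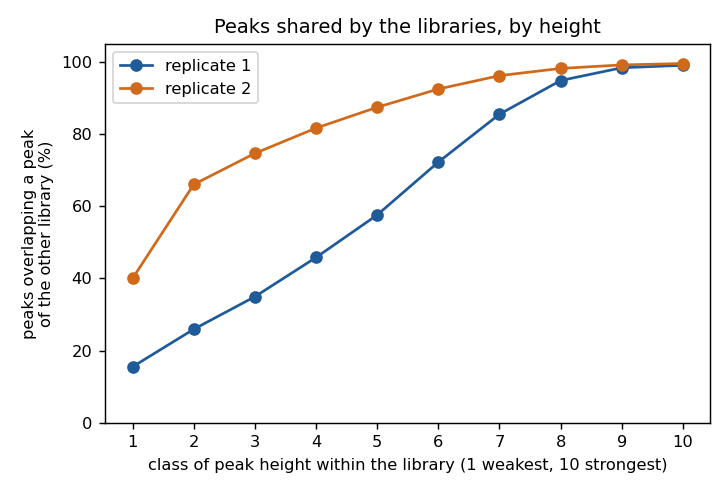
Share of the peaks of each replicate library that overlap a peak of the other (y axis, percent) in 10 classes of peak height from lowest to highest (x axis), with 1 point per class and a line per library. The share goes from 15.5% to 99.1% in replicate 1 and from 40.0% to 99.6% in replicate 2.

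Across the 177412 peaks paired between the libraries, heights gave a Spearman correlation of 0.848 and a Pearson correlation on the log2 scale of 0.890, with no p because peaks are not independent replicates. Heights in replicate 2 were lower, with a median log2 ratio of replicate 2 over replicate 1 of -0.32 and an SD of 0.70. Within 2-fold of that median lay 84.4% of the pairs, with 15240 peaks beyond it in favour of replicate 2 and 12461 in favour of replicate 1. Promoter peaks stood above the median of all pairs by 0.21 on the log2 scale and exonic peaks by 0.13, whereas intronic peaks stood at -0.11 and peaks between protein-coding genes at -0.06. The ratio also followed GC content, from -0.34 in the lowest of 10 classes to 0.25 in the highest.

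Promoters of lung fibroblast genes were open in both libraries more often than those of random lists. All 18 lung fibroblast genes had a shared promoter peak, among them Tcf21, a transcription factor gene of lung mesenchyme, Fgf10, a growth factor gene of lung budding, and the collagen genes Col1a1, Col1a2 and Col3a1. Random lists matched on promoter GC content gave 67.6%, with an adjusted p of 0.0035 from an unadjusted p of 0.0002, the smallest that 10000 random lists allow. This call held under all 7 alternatives. Shared promoter peaks were also found at 14 of 14 vascular endothelium genes (77.2% in random lists, adjusted permutation p = 0.113), 12 of 12 genes of myofibroblasts and smooth muscle (77.2%, 0.0849), 9 of 9 pericyte genes (76.4%, 0.265) and 7 of 7 genes of alveolar capillary aerocytes (76.8%, 0.398). They were found at 12 of 12 alveolar type 1 genes (87.5%, 0.520), 11 of 12 alveolar type 2 genes (66.6%, 0.146) and 12 of 12 lung epithelial transcription factor genes (86.0%, 0.440). None of these 7 lists passed the test against random lists. Apart from alveolar type 2 genes, all stood at 100%, the highest share possible, so the test could give no lower p. For alveolar type 1 genes that limit was an unadjusted permutation p of 0.386. A missing call therefore does not show that these promoters were open no more often than those of random lists.

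Germ cell, intestinal and posterior Hox genes stood below random lists. Of 8 germ cell genes, Dazl, which encodes an RNA-binding protein of germ cells, alone had a shared promoter peak (12.5% against 71.2% in random lists, adjusted permutation p = 0.0070). Of 7 intestinal epithelium genes, Lgr5, a Wnt target of stem cells, and Vil1, which encodes the microvillus protein villin, had one (28.6% against 79.3%, adjusted permutation p = 0.00875). Of 12 posterior Hox genes, the homeobox genes of the hind part of the body axis, 5 had one, namely Hoxa10, Hoxb13, Hoxc10, Hoxc13 and Hoxd10 (41.7% against 89.8%, adjusted permutation p = 0.0035). The germ cell call was lost with a 2.5 kb window (adjusted permutation p = 0.197), and the intestinal call was lost with that window, without matching and without replicate 2 (adjusted p up to 0.257). The posterior Hox call was lost without matching on GC content (adjusted permutation p = 0.118) and against random runs of neighbouring genes (p = 0.219), a test added after the data were seen.

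The other 24 lists did not pass. Shared promoter peaks were found at 10 of 11 ciliated cell genes (73.2% in random lists, adjusted permutation p = 0.413), 7 of 7 neuroendocrine genes (82.0%, 0.577), 6 of 10 genes of club and secretory cells (66.5%, 0.952) and 3 of 6 airway basal cell genes (77.0%, 0.287). Scgb1a1, the main secretory protein gene of club cells, had no shared promoter peak. Shared promoter peaks stood at 5 of 6 lymphatic endothelium genes (64.9%, 0.610), 4 of 7 mesothelium genes (68.9%, 0.807), 11 of 12 elastic fibre genes (80.8%, 0.594) and 15 of 16 genes of lung developmental signalling (86.7%, 0.713), where Shh, the hedgehog ligand gene, lacked one. Among blood lineages the counts were 7 of 12 for macrophages and monocytes (60.3%, 1), 5 of 8 for B cells (65.6%, 1), 5 of 12 for T and NK cells (63.4%, 0.329), 2 of 9 for neutrophils (58.1%, 0.142), 2 of 10 for erythroid cells (60.0%, 0.0840) and 3 of 6 for megakaryocytes and platelets (75.8%, 0.440). Among other tissues they were 2 of 10 for hepatocytes (54.0%, 0.0980), 5 of 9 for cardiomyocytes (79.2%, 0.335), 2 of 8 for skeletal muscle (63.7%, 0.0700), 9 of 10 for neurons (75.7%, 0.536), 2 of 7 for pancreatic acinar cells (58.6%, 0.287), 1 of 6 for kidney tubule and podocytes (65.5%, 0.0700) and 1 of 6 for epidermal keratinocytes (42.2%, 0.468). The 14 housekeeping genes (86.7%, 0.413), the 12 cell cycle genes (86.3%, 0.450) and the 11 anterior Hox genes (73.0%, 0.122) all had one. Like the neuroendocrine genes, these lists stood at the highest share possible, so the test could give them no lower p. Some lists that did not pass were called in other settings. Genes of T and NK cells, cardiomyocytes, acinar cells and kidney were called below random lists in the stronger 50% of peaks and in the shorter list, those of airway basal cells and hepatocytes in the stronger 50% and with a 500 bp window, and those of megakaryocytes and skeletal muscle with that window. Anterior Hox genes were called above random lists in the stronger 50%, and genes of myofibroblasts and smooth muscle with the 500 bp window. Without replicate 2, erythroid and kidney genes were called below random lists, and without matching erythroid and hepatocyte genes were. The tests were two-sided resampling percentiles over 35 lists, adjusted over the lists alone, and describe these 2 libraries, since genes are not replicates.

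Counting peaks across the gene and 10 kb on both sides brought out 8 lists with more shared peaks than random lists of equal gene length. Anterior Hox genes, which pattern the front part of the body axis and are active in lung mesenchyme, held 14.6 shared peaks per gene against 2.47, and lung developmental signalling genes held 29.2 against 9.06 (adjusted permutation p = 0.0035 for each, with an unadjusted p of 0.0002, the smallest that 10000 random lists allow). These means were taken on the square-root scale and squared back. In the anterior Hox list, Hoxa3, whose gene model of 44.3 kb spans its neighbours, held 46 and Hoxb3 held 24, while Hoxb1, active in the early hindbrain, held 2. In the signalling list, Rara, a retinoic acid receptor gene, held 54, Fgf9, a growth factor gene of the mesothelium and epithelium, held 9, and Fgfr2, the receptor gene for FGF10, held 393 in an annotated gene model of 2961 kb. Without Fgfr2, left out after its value was seen, the other 15 genes held 19.8 against 8.51 (adjusted permutation p = 0.0210). Both calls held under all 7 alternatives. Against runs of neighbouring genes, not matched on gene length, the anterior Hox list gave an unadjusted permutation p of 0.0250. The means on the square-root scale were 3.82 for the list and 2.28 for the runs. This p was not adjusted over the lists, so it does not show whether the call at an adjusted p would hold there.

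Alveolar and endothelial genes followed. Alveolar type 1 genes held 10.9 shared peaks per gene against 5.14 (adjusted permutation p = 0.0070), led by Rtkn2 with 18 and Clic5, a chloride channel family gene, with 17, and with 4 at Igfbp2. Aerocyte genes held 11.02 against 4.14 (adjusted permutation p = 0.00875), with 28 at Tbx2, a T-box factor gene, 17 at Kitl, the ligand gene of the KIT receptor, and 5 at Apln. Lung epithelial transcription factor genes held 10.3 against 4.09 (adjusted permutation p = 0.0154), with 19 at Foxa1, a pioneer factor gene of endoderm, 18 at Grhl2 and 5 at Irx2. Genes of elastic fibre and matrix assembly held 16.1 against 7.68 (adjusted permutation p = 0.0230), with 44 each at Ltbp2 and Fbn1, which encodes fibrillin 1, and 5 at Loxl2. Vascular endothelium genes held 13.9 against 6.85 (adjusted permutation p = 0.0315), with 41 at Flt1, a VEGF receptor gene, 27 at Pecam1 and 2 at Tie1. Housekeeping genes held 6.91 against 3.42 (adjusted permutation p = 0.0230), with 14 at Gapdh, 13 at Actb and 3 at Pgk1. Hepatocyte genes were the list below random lists, with 1.17 against 3.92 (adjusted permutation p = 0.0366), 6 peaks at Hnf4a, 3 at Cyp2e1 and none at Ahsg.

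Of these 9 calls, those of alveolar type 1 cells and lung epithelial transcription factors were lost with the shorter deposited list, without matching and with 50 kb flanks (adjusted p up to 0.104 and 0.352), and that of aerocytes with the stronger 50% of peaks, without matching and with 50 kb (up to 0.214). Those of elastic fibre genes (up to 0.0518), vascular endothelium (up to 0.0548) and housekeeping genes (up to 0.563) were lost with 50 kb flanks, the last 2 also over the gene body alone and the housekeeping call also without matching, while the hepatocyte call was lost in 5 of 7 alternatives, including without either replicate (up to 0.604).

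The remaining 26 lists did not pass. Lung fibroblast genes held 13.2 shared peaks per gene against 7.99 in random lists (adjusted permutation p = 0.0518), from 52 at Limch1 and 28 at Col14a1 down to 2 at Lum. This list was called above random lists without either replicate and without matching (adjusted p down to 0.0192). Genes of myofibroblasts and smooth muscle held 11.1 against 6.32 (0.0592), with 23 at Lgr6, 18 at Tgfbi and 6 at Cnn1. Alveolar type 2 genes, which make surfactant, held 7.75 against 5.28 (0.295), with 14 at Etv5, 13 at Lpcat1 and 4 at Sftpa1. Pericyte genes held 8.91 against 5.62 (0.295), with 21 at Notch3, 16 at Cspg4 and 4 at Trpc6. Mesothelium genes held 2.21 against 5.83 (0.152), with 6 at Upk3b, 5 at Krt19 and none at Gpm6a. Among airway lists, the most shared peaks lay at Aldh1a1 (11) and Cbr2 (8) for club cells, Rfx3 (16) and Tekt1 (13) for ciliated cells, Trp63 (16) and Ngfr (10) for basal cells, and Syp (6) for neuroendocrine cells. The fewest lay at Bpifa1 (2), Dnah5 (3), Krt17 (0) and Calca (2). Lymphatic endothelium genes ranged from 13 at Flt4 and 6 at Lyve1 to 0 at Ccl21a.

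Blood and other lists spread as widely. Pparg (21) and Cd68 (10) led the macrophage list, Elane (9) and Cxcr2 (5) the neutrophil list, Lck (14) and Cd2 (9) the T and NK list, Ebf1 (30) and Pax5 (21) the B cell list, Epor (8) and Klf1 (5) the erythroid list, and Itga2b (9) and Gp1bb (8) the megakaryocyte list. No shared peak lay at Ear2, S100a9, Gzma or Alas2, and 1 lay at Treml1. Ryr2 (20) and Tnni3 (7) led the cardiomyocyte list, Tnnt3 (8) and Ckm (6) skeletal muscle, Rbfox3 (35) and Grin1 (10) neurons, Cpa1 (4) and Cel (3) acinar cells, Slc12a1 (9) and Aqp2 (8) kidney, Cdx1 (8) and Lgr5 (8) intestine, Krt10 (3) and Lor (2) keratinocytes, Prm2 (7) and Ddx4 (5) germ cells, Aurkb (13) and Mki67 (11) the cell cycle, and Hoxd10 (5) and Hoxc10 (3) the posterior Hox list. The fewest lay at Myh6 (1), Myh1 (2), Neurod1 (2), Ptf1a (1), Slc22a6 (0), Alpi (2), Flg (0), Acr (0), Ccna2 (1) and Hoxa11 (1). The adjusted p of the lists not given a value here ran from 0.204 for megakaryocytes to 0.982 for cardiomyocytes, T and NK cells and posterior Hox genes.

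**Figure D2:**
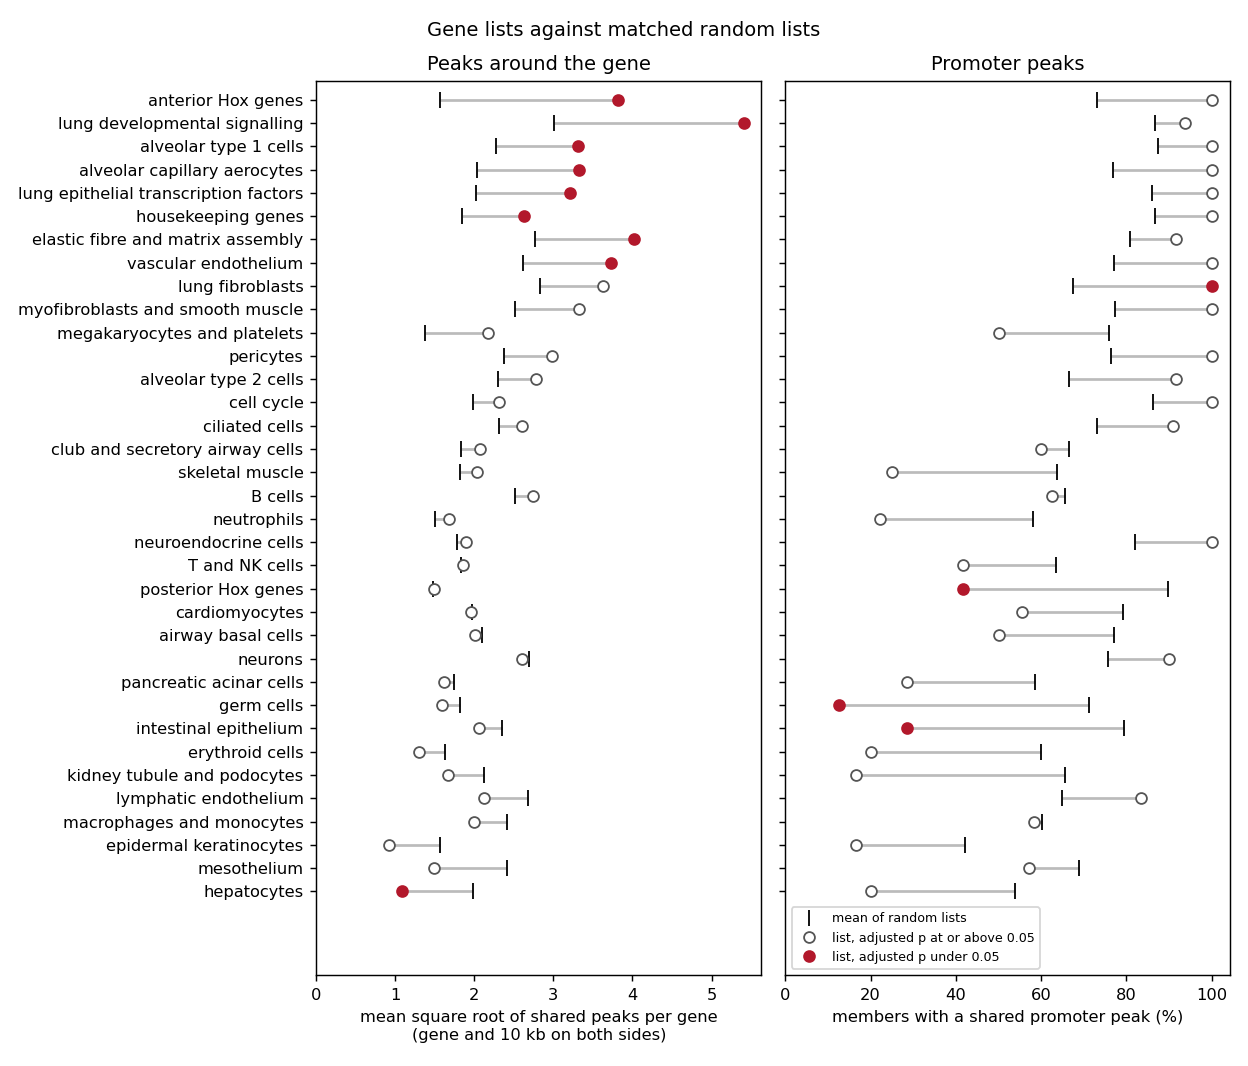
Fixed gene lists against random lists of genes, by share of members with a shared promoter peak (percent) and by shared peaks per gene within 10 kb (square-root scale), with 1 point per list. Lung fibroblasts stand at 100% promoter peaks and germ cells at 12.5%. Lung developmental signalling and anterior Hox genes stand at 5.41 and 3.82 on the square-root scale, which squared back are 29.2 and 14.6 shared peaks per gene. The signalling value includes Fgfr2, without which it is 19.8 shared peaks per gene.

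Sftpc, the surfactant protein C gene of alveolar type 2 cells, was chosen for a map after its values were seen. It lies on the minus strand of chromosome 14, 70520949 to 70524081, and 13 shared peaks lay from 10 kb before to 10 kb after it. The peak at its TSS, which spanned 70524101 to 70524520 in replicate 1 and 70524121 to 70524480 in replicate 2, had heights of 3.16 and 1.67. Another shared peak lay downstream of Sftpc at 70520041 to 70520300, with heights of 3.78 and 2.36. It spanned the start of Bmp1, which encodes a procollagen protease and begins at 70520234 on the minus strand. Upstream, towards Lgi3, the peak at 70526721 to 70527220 in replicate 1 overlapped the peak at 70527141 to 70527320 in replicate 2, with heights of 3.74 and 4.39. The replicate 1 peak also overlapped a replicate 2 peak at 70526641 to 70526800, with a height of 2.08. It was paired one to one with neither, so its height has no matched value in replicate 2.

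**Figure D3:**
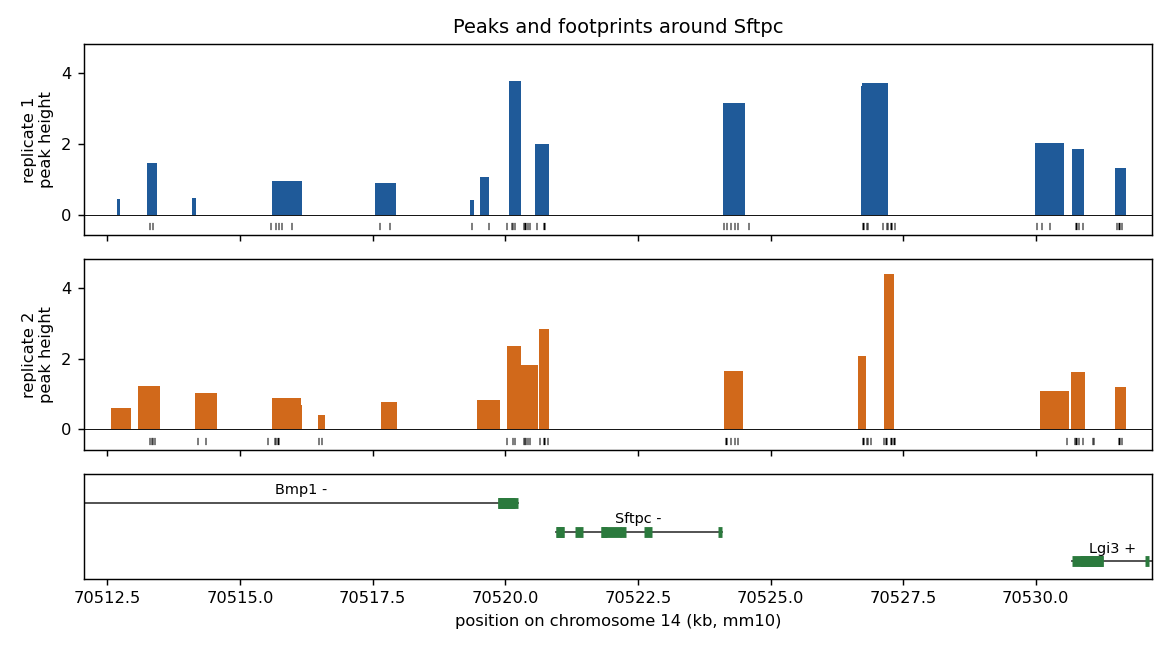
Peak heights (y axis, read-depth normalized) of replicate 1 and replicate 2 as bars over their positions on chromosome 14 (x axis, kb, mm10), with footprints as black ticks and the genes Bmp1, Sftpc and Lgi3 drawn beneath. The peak at the Sftpc TSS reaches 3.16 in replicate 1 and 1.67 in replicate 2, and the peak across the start of Bmp1 reaches 3.78 and 2.36.

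The comparison of heights between the libraries asked whether any cell type list stood higher in 1 of them. Posterior Hox genes did, in replicate 2. Heights at shared peaks around these genes gave a mean log2 ratio of replicate 2 over replicate 1 of 0.90 (1.87-fold, SD 0.22 across genes), centred on all shared peaks, against 0.17 in random lists of equal height. All 12 genes stood above 0, from 0.46 at Hoxc11 to 1.06 at Hoxa11 and 1.31 at Hoxa13, a gene of the distal limb and genital tubercle. At the strongest shared peak around Hoxa13, at chromosome 6, 52257041 to 52257220, heights were 1.84 and 3.68. The genes shared 20 distinct peaks on 4 chromosomes, 19 of which stood above 0. The adjusted p was 0.0070, from an unadjusted p of 0.0002, the smallest that the random lists allow. The call was made in 5 of 7 alternatives and lost with promoter peaks alone (5 genes, mean 0.69) and, after adjustment for GC content and height, with peaks outside promoters alone (10 genes, mean 0.76, adjusted p up to 0.0700).

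No other list passed this test. Random lists themselves stood above 0, so a count of genes above 0 is not a comparison with them. Their means were 0.18 for neuroendocrine and neuron genes and 0.20 for cardiomyocyte genes. They were 0.21 for T and NK cell genes and for macrophages and monocytes, and 0.15 for alveolar type 2 genes. Farthest above 0 after the posterior Hox genes were neuroendocrine genes at 0.63 (adjusted permutation p = 0.0826, 7 of 7 genes above 0), with Resp18 at 0.95 and Scg5 at 0.90, and cardiomyocyte genes at 0.49 (adjusted p = 0.25, 8 of 9 genes above 0), with Nppa at 1.24 and Myh6 at 1.02. Neuron genes stood at 0.47 (adjusted permutation p = 0.135, 10 of 10 genes above 0). Farthest below 0 were T and NK cell genes at -0.15 (adjusted permutation p = 0.0826, 5 of 11 genes below 0), with the co-receptor gene Cd8a at -1.29 and the CD3 chain gene Cd3d at -1.24. The median of this list had the opposite sign, 0.04. Alveolar type 2 genes stood at -0.15 (adjusted permutation p = 0.0826, 7 of 12 genes below 0), with Lamp3, a lysosomal and lamellar body protein gene, at -1.15 and Sftpa1 at -0.41. Genes of macrophages and monocytes stood at -0.13 (adjusted permutation p = 0.120, 7 of 11 genes below 0), with the lysozyme gene Lyz2 at -0.94 and Itgax at -0.62. After adjustment of the ratio for GC content and height, added after the data were seen, the T and NK list stood at -0.24 (adjusted permutation p = 0.0350). Other settings called further lists. With promoter peaks alone, genes of alveolar type 2 cells, macrophages, T and NK cells and megakaryocytes were called lower in replicate 2, and those of neurons and ciliated cells higher (lowest adjusted p over the alternatives 0.0105, 0.0217, 0.0050, 0.0450, 0.0430 and 0.0250). With 50 kb flanks, alveolar type 2 and lung fibroblast genes were also called lower in replicate 2, with the stronger 50% of peaks vascular endothelium genes were (adjusted permutation p = 0.0455), and by rank percentile T and NK genes were called lower and neuroendocrine genes higher. After the adjustment for GC content and height, none of these lists but T and NK cells passed. Alveolar type 2 genes then stood at 0.02 (adjusted permutation p = 0.666) and macrophage genes at -0.04 (adjusted p = 0.431), whereas neuroendocrine genes stayed at 0.58 (0.0600), neuron genes at 0.44 (0.0903), lung fibroblast genes at -0.10 (0.0600) and vascular endothelium genes at -0.09 (0.0691). The percentile was two-sided over 35 lists, adjusted over the lists alone, and compares 2 libraries, not conditions.

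**Figure D4:**
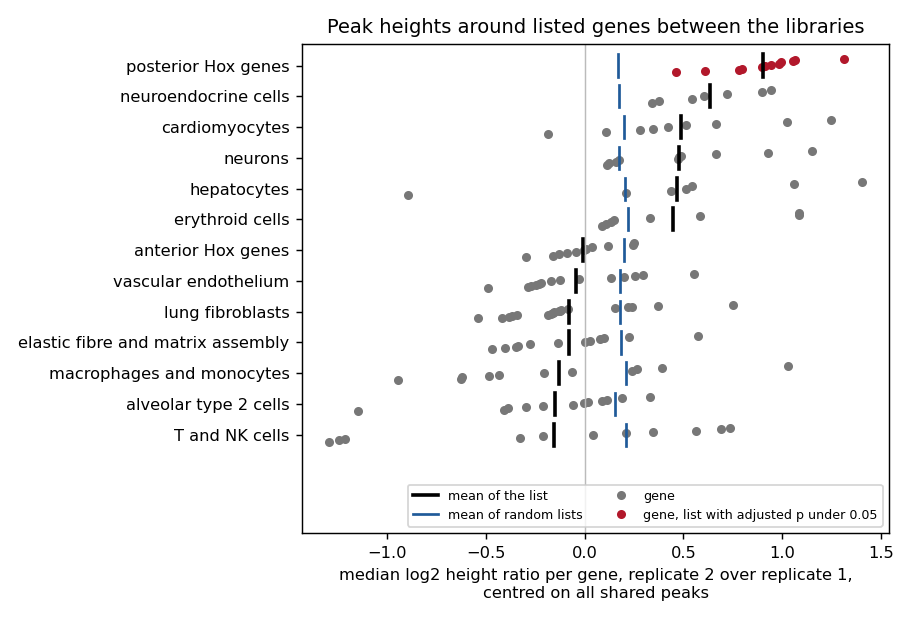
Log2 ratio of peak height, replicate 2 over replicate 1 and centred on all shared peaks (x axis), for genes of fixed lists (y axis). Only the lists with the lowest and the highest means and the anterior Hox list are drawn, not every fixed list. Grey dots are genes, black is the list mean and blue is the mean of random lists. The posterior Hox list, in red, stands at 0.90 with all 12 genes above 0.

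Footprints, short stretches inside open chromatin where a bound protein keeps DNase I from cutting, were compared next. Of the footprints of replicate 1, 50.03% (332796) overlapped a footprint of replicate 2, and of those of replicate 2, 52.1% (322105) overlapped 1 of replicate 1, a mean of 51.1% ± 1.48. As for the peaks, both shares count the same overlaps, so this SD is not a spread of independent values. With 1 list shifted by 200 bp the shares were 8.40% and 8.89%. As the median peak was 180 bp wide, this shift moves many footprints out of open chromatin. The shifted shares therefore do not give the overlap to be met within a peak by position alone, which was not measured. Within shared peaks, 15.5% and 17.6% of the bases were footprinted in replicate 1 and replicate 2, and a mean of 59.0% of the footprints overlapped. Peaks of the own library held 87.2% and 84.3% of the footprints. A footprint was found in 78.9% and 87.8% of the peaks, from 24.1% and 57.1% in the lowest of 10 height classes to 99.9% and 99.99% in the highest. Bases footprinted in both libraries made up 9.48% of the 41445789 bases of shared peaks.

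Binding sequences of the insulator protein CTCF and of NRF1, an activator of mitochondrial genes, were footprinted in both libraries almost wherever they occurred in shared peaks. For CTCF this held at 4484 of 4938 matches (90.8%, 95% Wilson interval 89.97% to 91.6%), against a median of 12.5% for shuffled versions of the sequence, and for NRF1 at 412 of 449 (91.8% against 18.2%). The cAMP response element stood at 1004 of 1419 (70.8% against 7.15%), the site of CEBP factors, which act in alveolar type 2 cells and macrophages, at 92 of 144 (63.9% against 6.18%), and YY1 at 133 of 297 (44.8% against 6.06%). The site of HNF1 factors stood at 10 of 32 (31.2%, interval 18.0% to 48.6%, against 0%). Each of these 6 motifs gave a one-sided rank p of 0.0099, the smallest that 100 shuffled versions allow, and an adjusted p of 0.0479 over 29 motifs, adjusted over the motif list alone. At an unadjusted p under 0.05 there were 9 motifs. No motif passed without replicate 1, with peaks over 1 kb from a TSS or with the whole match in a footprint, where 5, 4 and 5 motifs stood at an unadjusted permutation p of 0.01 or lower and 6 at that p would pass. YY1 also missed without replicate 2 (adjusted permutation p = 0.0638) and against the footprinted share of the same peaks (adjusted p = 0.128).

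The strongest footprinted match of each called motif had a place in the genome. For NRF1 it was GCGCATGCGC at chromosome 7, 45395732 to 45395741, in a UTR of Snrnp70, a gene of the spliceosome, 5 bp from the TSS. For YY1 it was AAGATGGCGGC at chromosome 9, 108002634 to 108002644, in a UTR of Ip6k1, and for CEBP it was GTTGCGTAAT at chromosome 19, 5295468 to 5295477, 18 bp from the TSS of Sf3b2. For the cAMP response element it was TGACGTCA at chromosome 6, 86669517 to 86669524, 360 bp from the TSS of Mxd1. For CTCF it was CCACCAGAGGGCGC at chromosome 8, 20424868 to 20424881, outside protein-coding genes, 61665 bp from Gm15319. For HNF1 it was GTTAATGATTAA at chromosome 5, 28501221 to 28501232, outside protein-coding genes, 33971 bp from the TSS of Shh, in a peak with heights of 3.69 and 2.09.

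The other motifs did not pass. Nuclear factor I (NFI), a family of lung maturation factors, stood at 213 of 295 matches (72.2% against 8.92%, adjusted permutation p = 0.0716), and passed against 1000 shuffled versions, a number chosen after the data were seen (adjusted p = 0.00966). The site of interferon regulatory factors stood at 7.20% against 3.41% (adjusted permutation p = 0.0716). It passed without replicate 2 (18.1% against 8.51%, adjusted permutation p = 0.0479) and not against 1000 shuffled versions (adjusted p = 0.125). The GC box of the SP and KLF families stood at 3528 of 4838 (72.9% against 43.7%, adjusted permutation p = 0.0716), above all of its 44 shuffled versions, whose number allows no unadjusted p under 0.0222. NFY stood at 16.4% against 7.50% (adjusted permutation p = 0.230) and the E-box bound by TCF21 at 13.7% against 7.28% (adjusted p = 0.243). The lowest differences belonged to steroid receptor sites (NR3C, 1.23% against 8.34%), forkhead sites (1.86% against 3.76%) and AP-1 sites (4.86% against 6.45%). With too few shuffled matches, 4 motifs were not tested. Of these REST, a repressor of neuronal genes, was footprinted at 132 of 153 matches (86.3%), RFX at 46 of 62 (74.2%), ZNF143 at 110 of 232 (47.4%) and P53 at 0 of 16, which allows a share of up to 19.4%. Intervals cover counting error only.

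**Figure D5:**
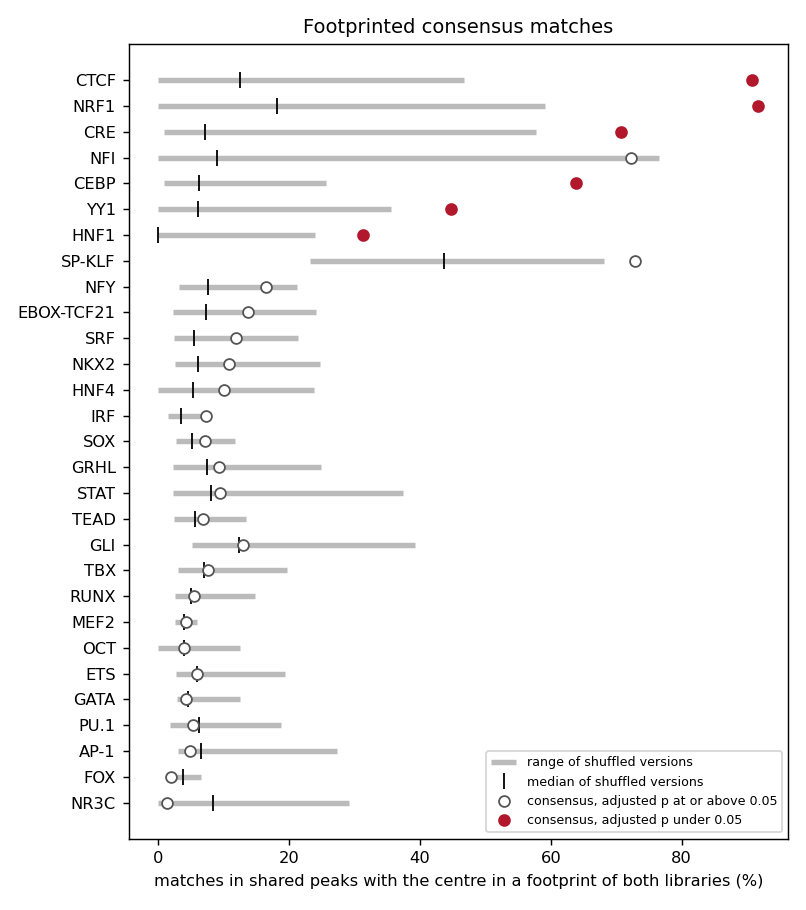
Percent of the matches of each motif in shared peaks whose centre lies in a footprint of both libraries, with the same percent for shuffled versions of the sequence beside it. CTCF stands at 90.8% against a shuffled median of 12.5%, and NR3C at 1.23% against 8.34%.

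Chromosome X, present as 1 copy in males, held fewer peaks than any autosome. It had 44.6 and 33.7 peaks per Mb, against autosomal medians of 117 and 87.9 and lowest autosomal values of 94.9 and 69.3. Its density was 0.382 ± 0.00252 (SD, 2 libraries) of the autosomal median. A peak lay at the TSS of 57.9% and 56.1% of the protein-coding genes of chromosome X, against 75.1% and 73.4% on autosomes. Median heights were 0.301 and 0.292 on chromosome X against 0.529 and 0.536 on autosomes, a ratio of 0.557 ± 0.0171. Chromosome Y held 123 and 116 peaks. The density ratio was 0.227 for the stronger 50% of peaks.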

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

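Of the settings below, the stronger 50% of 1 library against all peaks of the other, the ratio adjusted for GC content and height, peaks outside promoters, the excess over the footprinted share, 1000 shuffled versions, shuffles with equal CpG number, runs of neighbouring genes and the signalling list without Fgfr2 are tests chosen only after the result was seen. No paired analysis was possible because the series has only 1 group. Of 55 alternative values, 28 counted as the same as the main value, 25 moved, 1 was weaker and 1 reversed. Single lists counted as the same on the same side of their threshold, and shares and densities within the SD of the libraries. Numbers of calls counted as the same when similar, whichever lists or motifs were called. Without matching, 4 lists were called by promoter peaks, 2 of them among the main calls. Around the gene 6 were, 5 of them among the main calls. The cause was not tested unless it is given here. Shared peaks were 64.2% to 79.7% in 4 other settings, against 73.3% ± 14.5, an SD widened by unequal numbers of peaks, since equal numbers gave 76.0% and 76.2%, and reached 93.5% with the stronger 50% of 1 library against all peaks of the other. With so wide an SD, that these 4 settings counted as the same says little. Spearman correlation of heights dropped from 0.848 to 0.785 in the stronger 50%, which spans a narrower range of heights by construction. The promoter share of peaks was 10.7% with 500 bp, 20.8% with 2.5 kb, 20.9% with all annotated genes, 21.98% in the stronger 50% and 18.96% in the shorter list, and ranged from 13.3% to 16.6% with each replicate left out. Wider windows and more genes take in more peaks by construction. With 2 libraries, leaving 1 out always gives a value within their SD of the mean. For the promoter share and the chromosome X density these alternatives therefore counted as the same by construction. Chromosome X density was 0.227 in the stronger 50% and 0.351 in the shorter list, and 0.380 to 0.384 with each replicate left out. By promoter peaks, against 4 calls, 11 lists were called in the stronger 50%, 8 in the shorter list, 9 with 500 bp, all including the same 4, 2 with 2.5 kb, and 4 to 5 with each replicate left out. By peaks around the gene, against 9 calls, 2 lists (anterior Hox genes and lung developmental signalling) were called with 50 kb, and 9 with either replicate left out, 8 of them the same. Between libraries, against 1 call, 6 lists were called with promoter peaks alone, without the posterior Hox list, 3 with 50 kb, 3 by rank percentile, 2 in the stronger 50%, 2 with adjustment for GC content and height, and 0 with that adjustment and peaks outside promoters alone. Against runs of neighbouring genes, the posterior Hox list lost its promoter call (permutation p = 0.219), and its peaks around the gene changed from above to below the random mean, with no call in either (p = 0.216). Footprint overlap was 36.5% with a reciprocal overlap of 50% and 59.0% inside shared peaks. Motif calls, against 6, numbered 0 to 6 with each replicate left out, 0 without replicate 1 and 6 without replicate 2 (with interferon regulatory factors and without YY1), 0 for peaks over 1 kb from a TSS, 0 with the whole match in a footprint, 7 with 1000 shuffled versions and 7 with equal CpG number (the same 6 and NFI), and 6 by the excess over the footprinted share (with NFI and without YY1). In the settings with 0 calls too few motifs stood at a p of 0.01 or lower for any to pass, and more shuffled versions were not run there. Some called motifs fell below their highest shuffled version, namely YY1 in all 3 settings (54.9% against 58.8% without replicate 1, 20% against 46.7% over 1 kb from a TSS, 21.5% against 32.3% with the whole match), HNF1 without replicate 1 (37.5% against 44%) and the cAMP response element over 1 kb from a TSS (57.9% against 61.3%). Peaks found in 1 library alone had a median of 62 cleavages, and whether depth limits them was not tested. The simulated shift of 0.5 SD between libraries was called in 0 of 30 lists, so shifts of that size would be missed.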

Other observations

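In this part, the tests of depth, of the share of cleavages in accessible sites, of GC content and height, and of the copy number of chromosome X were chosen only after the result was seen, as were the sites and peaks described first.

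Binding sequences of known regulators were footprinted at the promoters of some listed genes. Sites of REST, the repressor of neuronal genes, were footprinted in both libraries at 3 genes of the neuron and neuroendocrine lists. They were TTCAGCACCTCGGACAG in an intron of Chga, the chromogranin A gene (chromosome 12, 102555238 to 102555254), TTCAGCACCGCGGACAG in an intron of Snap25, a synaptic vesicle fusion gene (chromosome 2, 136714338 to 136714354), and TTCAGCACCTCGGACAG in a UTR of Grin1, an NMDA receptor gene (chromosome 2, 25319018 to 25319034). The peaks around them had heights of 1.70 and 2.29, 2.32 and 3.53, and 1.12 and 1.30. A GLI site, TGGGTGGTC, was footprinted in a UTR of Ptch1, the hedgehog receptor and a GLI target (chromosome 13, 63573465 to 63573473), in a peak with heights of 1.20 and 1.18, although over all shared peaks GLI matches were footprinted about as often as shuffled versions (12.98% against 12.4%, adjusted permutation p = 0.612). At Etv5, a transcription factor gene of alveolar type 2 cells, 3 sites of the CCAAT-binding factor NFY were footprinted in a promoter peak with heights of 27.8 and 17.6. Col1a1 had a footprinted NFY site (AGCCAATCA, chromosome 11, 94936149 to 94936157, 71 bp from the TSS) and a footprinted CTCF site in an intron (CCACTAGGTGGCGG, chromosome 11, 94937174 to 94937187). Across all listed genes, 17 NFY sites at 15 genes, 25 GC boxes at 22 genes, 9 cAMP response elements, 7 CTCF sites and 5 SRF sites were footprinted in both libraries. No test was run on these counts.

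The shared peaks with the most unequal heights lay outside promoters. Higher in replicate 1 were peaks 226531 bp from Ptprd (chromosome 4, 75857811 to 75858040, heights 2.28 and 0.192) and 315117 bp from Cited2 (chromosome 10, 17407981 to 17408220, heights 2.06 and 0.212). Higher in replicate 2 was a peak in Zim2, annotated as a processed transcript, 28855 bp from a TSS of Zim1, an imprinted zinc finger gene (chromosome 7, 6659714 to 6659920, heights 0.183 and 1.02). Among the 5 peaks with the largest ratio in favour of replicate 2, 3 lay wholly in repeats (100% of their bases), among them a peak in a coding exon of Gm11168 (chromosome 9, 3006800 to 3006920, heights 0.488 and 2.94).

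Replicate 1 had 284760 peaks and replicate 2 had 215093, a ratio of 1.32. Deeper sequencing of replicate 1 is argued against by the depths, since replicate 1 had 0.877 of the depth of replicate 2 if the step in height is 1 cleavage scaled to depth. Regions of replicate 2 that pass the FDR without a peak placed in them are argued against as well, since 9.63% of the peaks found in replicate 1 alone overlapped sequence listed at an FDR up to 0.05 in replicate 2, against 4.60% after a shift of 1 Mb. A larger share of the cleavages of replicate 1 inside accessible sites stays open. Heights relative to depth were lower in replicate 2 in 10 of 10 classes of GC content, but this follows from the overall median and the trend with GC content, both seen before, and does not test it. As the series has 1 group, no biological explanation was tested.

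Posterior Hox genes stood higher in replicate 2 than in replicate 1. GC content and height of the peaks are argued against as the whole cause, since the list stayed past the threshold after adjustment for both (adjusted permutation p = 0.0070) with a mean log2 ratio of 0.73 (SD 0.34) in place of 0.90 (SD 0.22). Random runs of neighbouring genes reached the value with permutation p = 0.00040. These runs were not matched on height, on the distance between genes or on the peaks they share. They therefore cannot decide whether peaks shared by neighbouring genes made the list stand out. Counted once each, the 20 distinct peaks lay on 4 chromosomes and 19 stood above 0, but no test was run on them. With the adjustment and peaks outside promoters alone the list no longer passed (adjusted permutation p = 0.0700), where 10 genes were left, 8 of them above 0, with a mean of 0.76 and a wider SD of 0.69 in place of 0.22, and promoter peaks alone left 5 genes (mean 0.69, SD 0.45, adjusted p = 0.0618). A difference between the animals or tissue samples stays open as a hypothesis, and as the series has 1 group, no biological explanation was tested.

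Chromosome X held 0.382 ± 0.00252 of the autosomal peak density. Repeats that hold few peaks are argued against as the whole cause, since the ratio outside repeats was 0.477 ± 0.00566, although repeats cover 46.8% of chromosome X and 33.5% of autosomes. Few genes are argued against likewise, since the ratio per gene was 0.543 ± 0.000702. A single copy of chromosome X cannot be told apart from other causes, since dividing autosomal heights by 2 left 0.742 ± 0.0190 of the autosomal peaks above the 5th percentile of height, but 0.891 above the 1st and 0.460 above the 25th, and the peak caller's own minimum is not given in the sources used here. With the lowest height as minimum no autosomal peak was removed, which decided nothing, and no biological explanation was tested.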
